A study of Mus musculus with 4 samples.

How the data were processed

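CD45int CD11b+ cells were sorted by FACS from the brains of transplanted mice treated with antibiotics or vehicle, and total RNA was labelled with biotin for Affymetrix Clariom S arrays, per the labels' protocols. Each of the 4 arrays is 1 sample. Groups and replicate numbers (vehicle 1 and 5, antibiotics 8 and 9) come from the sample titles, and the design text describes 2 biological replicates per group. No replicate number is shared between groups, so none pairs the arrays.

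The authors deposited 1 table of log2 values for the 4 arrays. The submitters' processing notes name oligo and RMA, without versions or parameters. RMA corrects the background, quantile-normalizes probes and summarizes them per probe set on the log2 scale, so differences between arrays in total signal are largely removed, and ratios of dim genes can be compressed. Scanner files were not used here, and the genome build is not given in the sources used here. The values were used as deposited.

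Of 22203 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2631 had none. The Entrez identifiers of all 19572 matched the GRCm38.p6 gene table, which was used for names only, and 0 symbols changed. Where a gene had several probe sets, the one with the highest mean over all 4 arrays was kept, and 67 were left out, which gave 19505 genes. No filter on dim genes was applied. Probe sets with no gene name were tested apart: 0 of 2631 had an adjusted p under 0.05, with 83 at an unadjusted p under 0.05.

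Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided) for antibiotics minus vehicle, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SE is the moderated standard error, with 4.56 prior degrees of freedom added to 2 residual ones, and its median over genes was 0.31. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333, so none was run. Figures were drawn with matplotlib 3.10.9.

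There were 33 gene lists, fixed before the data were examined: 6 primary lists, 16 secondary lists and 11 lists of markers of other cells. Of these other cells, only CD11b+ ones such as border-associated macrophages, monocytes, neutrophils and some NK and dendritic cells could enter a CD45int CD11b+ gate, the CD45-high ones only at its edge, and the sort should remove neurons, astrocytes, oligodendrocytes, endothelial cells, erythroid cells and most T and B cells. All are named in the report with their results. The lists held 597 distinct measured genes, and 72 symbols were not carried by the annotation used, Cd74 and Nfkb1 among them. Each list was tested against all other genes with limma's camera with a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation, which also reads its p from the residual degrees of freedom alone, camera on ranks and fry were run beside it. A list's median log2 fold change was also set against 10000 random lists of the same size matched on mean expression.

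The named genes follow a rule fixed at the same time: the 15 largest changes per direction among genes past the threshold, or, where fewer than 10 pass, the 10 per direction with the smallest unadjusted p, without overlap of the arrays and with a mean above the median of all genes (predicted genes and olfactory or vomeronasal receptors not named). Up to 4 members per list with the smallest p, and a set of genes named whatever their values, were added.

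The tests were run first on simulated data for the comparison of 2 against 2 over 19505 genes, with variances drawn from the fitted distribution. With the spread of all 4 arrays, 0 of 50 genes changed 2-fold, 13 of 50 changed 4-fold, 42 of 50 changed 8-fold and 47 of 50 changed 16-fold were recovered, with 7 false calls. With the spread of the antibiotics arrays alone the recovered genes were 36, 50, 50 and 50, with 6 false calls. A shift of 0.5 of the homeostatic microglia list was called at the spread of all 4 arrays and a shift of 0.3 was not. At the spread of the antibiotics arrays alone the shift of 0.3 was also called. The simulation drew each gene on its own, with the same variance on every array. On the real arrays the SD of deviations was 0.70 on vehicle replicate 1 and 0.26 to 0.34 on the others. Members of some lists also moved together, with an estimated correlation of 0.72 for ribosomal proteins. The simulated recoveries and false calls may therefore not hold for these arrays.

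The alternatives were quantile normalization of the 4 columns, cyclic loess, centring each array on its median, leaving out genes at or under the 95th percentile of olfactory, vomeronasal, taste and trace amine receptor genes, leaving out the lowest 25% of genes, trend and robust moderation, array weights, the mean of a gene's probe sets, an ordinary test without moderation, an unadjusted p with a 1.5-fold change, and leaving out each array in turn. For the lists, the trend and robust setting used only camera's variance trend, without the robust step.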

Results

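The series measured gene expression in CD45int CD11b+ cells, the gate that takes in microglia, sorted from mouse brain after allogeneic haematopoietic cell transplantation (allo-HCT). Mice received antibiotics or vehicle from day -13 to day -1, were transplanted on day 0, received the same treatment from day 1 to day 14, and were harvested on day 14. The title of the series names acute graft-versus-host disease of the central nervous system and a metabolite of gut bacteria. The comparison asks how the sorted brain cells of transplanted mice differed when the gut bacteria had been treated with antibiotics. There were 4 arrays, 2 from vehicle-treated mice (replicates 1 and 5) and 2 from antibiotic-treated mice (replicates 8 and 9), described as biological replicates. Each Clariom S array gave log2 values for 22203 probe sets, and 19505 named genes were tested. The medians over all probe sets were 5.25 and 5.39 for vehicle replicates 1 and 5, and 5.44 and 5.38 for antibiotics replicates 8 and 9. The number of arrays limits the precision of every value.

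Genes that identify microglia were at high signal on all 4 arrays. P2ry12, a purinergic receptor of resting microglia, had a log2 value of 10.92 ± 0.08 with vehicle and 10.71 ± 0.06 with antibiotics (SD, n = 2 each). Itgam, which encodes the CD11b used in the sort, had 9.76 ± 0.11 and 9.91 ± 0.01, and Ptprc, which encodes CD45, had 9.81 ± 0.05 and 9.52 ± 0.01. Sall1, a transcription factor of microglial identity, had 8.08 ± 0.12 and 8.35 ± 0.13. Other genes separated vehicle replicate 1 from the rest. Tmem119, a microglial surface protein, was 7.86 on that array against 9.25, 8.76 and 8.88 on vehicle replicate 5 and antibiotics replicates 8 and 9, and Trem2, a lipid-sensing receptor, was 7.91 against 8.96, 8.58 and 8.56.

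Over all genes, vehicle replicate 1 correlated with the other arrays at a Pearson r of 0.892 to 0.895, while the other 3 arrays correlated with each other at 0.969 to 0.981. These correlations run across genes, which are not independent replicates. The first principal component, with 75.1% of the variance, separated vehicle replicate 1 from the rest. The vehicle arrays were at least 2-fold apart in 3287 genes and the antibiotics arrays in 132. Olfactory, vomeronasal, taste and trace amine receptor genes, 1463 in all, had a median of 4.10 on vehicle replicate 1 and of 3.50 to 3.59 on the others. Among genes with a mean log2 value under 3 on the other 3 arrays, vehicle replicate 1 lay above them by a median of 0.75. Its median deviation was -0.39 among genes between 6 and 8 and -0.20 over 9. Vehicle replicate 1 did not set these bins, so its lower correlation alone would also raise it in dim bins and lower it in brighter ones.

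**Figure D1:**
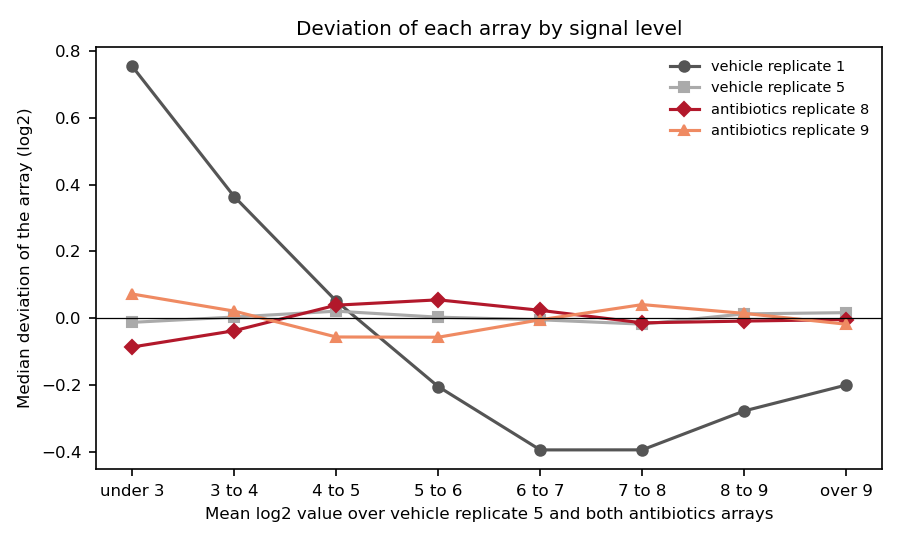
Median deviation of each array (log2, vertical axis) within bins of the mean log2 value over vehicle replicate 5 and both antibiotics arrays (horizontal axis), with 1 line per array. Vehicle replicate 1, which did not set the bins, runs from 0.75 in the dimmest bin to -0.39 in the bins between 6 and 8 and -0.20 over 9. The other 3 arrays, whose mean set the bins, stay near 0.

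No gene passed the threshold between antibiotics and vehicle. Among the genes named for the smallest p with both antibiotics arrays above both vehicle arrays, Dusp1, a phosphatase that inactivates MAP kinases, had a log2 value of 4.90 ± 0.04 with vehicle and 6.24 ± 0.22 with antibiotics (SD, n = 2 each), a log2 fold change of 1.34 ± 0.28 SE. Ahsa1, an activator of the Hsp90 chaperone, had 5.14 ± 0.73 and 6.98 ± 0.19, a log2 fold change of 1.83 ± 0.40 SE. Vhl, the substrate-binding part of the ubiquitin ligase that degrades HIF alpha subunits, had a log2 fold change of 1.36 ± 0.30 SE, and Ninj1, which ruptures the plasma membrane in lytic cell death, 1.22 ± 0.31 SE. The actin-binding gene Lasp1 (1.28), the nuclear pore gene Nup155 (1.23) and Ttc28 (1.55), Wdsub1 (1.41) and Sirpb1c (1.12) were further genes on the higher side by log2 fold change. Snx17, an endosomal sorting gene with 5.78 ± 0.07 and 6.98 ± 0.21, completed the 10 genes.

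On the lower side, Panx1, a channel that releases ATP, had 6.23 and 5.97 on vehicle replicates 1 and 5 and 5.23 and 4.76 on antibiotics replicates 8 and 9, a log2 fold change of -1.10 ± 0.31 SE. Cask, a synaptic scaffold protein, had -1.28 ± 0.36 SE, and Smarca5, a chromatin remodelling ATPase, had 9.02 ± 0.16 with vehicle and 8.09 ± 0.10 with antibiotics (SD, n = 2 each). Cxcl13, a chemokine that attracts B cells, had 6.34 ± 0.32 and 5.36 ± 0.09. The thrombin receptor gene F2r had a log2 fold change of -0.93, and Fkbp5, a co-chaperone induced by glucocorticoids, had -0.86. Echdc1 (-1.28), Cobll1 (-1.13) and Efcab7 (-0.85) had the log2 fold changes in brackets, and the amino acid transporter gene Slc6a17 had 7.68 ± 0.32 and 6.69 ± 0.16.

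Under limma, 0 of 19505 genes had an adjusted p under 0.05, and each of these 20 genes had an adjusted p of 0.868. At an unadjusted p under 0.05 there were 569 genes, 413 higher and 156 lower with antibiotics, where 975 would be expected by chance. The ordinary test without moderation of the variance also passed 0 genes, with 732 at an unadjusted p under 0.05. At least 2-fold apart without overlap of the arrays were 242 genes on the higher and 82 on the lower side (74.7% higher). That share was 61.2% after quantile normalization, 63.9% after cyclic loess and 51.1% with each array centred on its median, and 93.5% and 87.9% under the filters on dim genes by chemosensory level and by the lowest 25%. The arrays of the groups did not overlap in 35.0% of all genes, and chance gives 33.3%. Leaving out vehicle replicate 1 gave 67 genes past the threshold, leaving out vehicle replicate 5 gave 5950, and leaving out either antibiotics array gave 0. Of the 20 genes named above, 8 passed without vehicle replicate 1 (Dusp1, Lasp1, Ahsa1, Nup155, Vhl, Snx17, Wdsub1 and Cask), all 20 passed without vehicle replicate 5, and 0 passed without either antibiotics array. Over all genes 55.2% were higher with antibiotics and the median log2 fold change was 0.05, and random lists matched on mean expression to the gene lists had median values of -0.08 to 0.14, above 0 for 29 of the 33 lists. In 9 of the 20 named genes the mean of the dimmer group lay under the 95th percentile of the chemosensory receptor genes (5.16). Of all 160 genes named for this comparison or its lists, the log2 fold change moved by over 1.5 times in 80 without vehicle replicate 1, in 68 without vehicle replicate 5 and in 22 and 26 without antibiotics replicates 8 and 9. Both group means lay under 5.16 in 30 of the 160 genes, so their differences in log2 value are not read as folds of transcript: Bbox1, Ccr2, Fabp5, Ptgs2, Ikbkg, C2, Gla, Ctsk, Pfkp, Hk1, Cyp1b1, Nlrc4, Gria4, Gria2, Bub1, Ier2, S100a8, Ngp, Il2rb, Klrd1, Cd3g, Cd79b, Vpreb3, Flt3, Itgae, Sox9, Nefl, Mog, Cspg4 and Klf1. In another 36 genes 1 of the group means did, so their differences are not read as exact folds of transcript either. Among these were Dusp1, Ahsa1, Vhl, Sirpb1c and Wdsub1 on the higher side and Panx1, Echdc1, Cobll1 and F2r on the lower side.

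**Figure D2:**
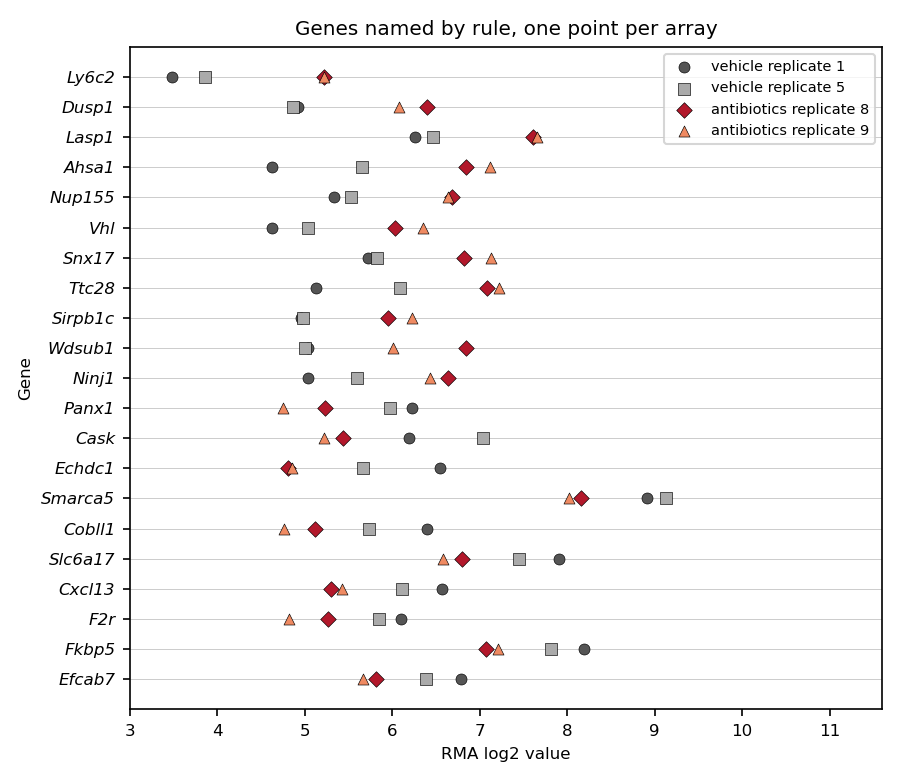
RMA log2 value (horizontal axis) of Ly6c2 and of the 20 genes named for the smallest p without overlap (vertical axis), with 1 point per array. Both antibiotics arrays lie on one side of both vehicle arrays in every row by the rule of choice, and none of the genes had a limma adjusted p under 0.05; Ly6c2 stands at 3.49 and 3.86 with vehicle and at 5.22 and 5.21 with antibiotics.

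Homeostatic microglial genes had higher values with antibiotics in 21 of the 24 measured members, and 0 passed the test one by one. The mean over the list was 8.94 and 9.24 on vehicle replicates 1 and 5, and 9.32 and 9.36 on antibiotics replicates 8 and 9. Cx3cr1, the fractalkine receptor, had 8.81 ± 0.12 and 9.37 ± 0.11 (SD, n = 2 each), and Olfml3 had 8.45 ± 0.32 with vehicle and 9.01 on both antibiotics arrays. The log2 fold change of Sparc, a matrix protein made by microglia, was 0.53 ± 0.27 SE, and that of the transcription factor Mef2c was 0.46 ± 0.28 SE. P2ry12 stood on the other side with -0.21 ± 0.27 SE, while Tmem119 and Sall1 each had 0.27. The median log2 fold change of the list was 0.27, with an adjusted p of 0.201 by limma's camera. With an estimated correlation the camera adjusted p was 0.856. That estimate was -0.0026, under the preset 0.01, so the p rose because it was read on 2 residual degrees of freedom. With camera's variance trend, without robust moderation, the adjusted p was 0.00824, past the threshold and the lowest over the alternatives. The median was 0.07 without vehicle replicate 1.

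Genes of disease-associated microglia had a median log2 fold change of 0.25, with 13 of 20 measured members higher with antibiotics. Itgax, which encodes CD11c, had 5.91 and 6.08 on the vehicle arrays and 6.99 and 6.94 on the antibiotics arrays, a log2 fold change of 0.97 ± 0.27 SE. Apoe, an apolipoprotein, had 8.73 ± 0.94 and 9.62 ± 0.29 (SD, n = 2 each), and its vehicle values were 8.06 and 9.39. Fabp5 had a log2 fold change of 0.73 ± 0.38 SE, Lgals3 0.47 ± 0.31 SE and Trem2 0.13 ± 0.39 SE, which was -0.0024 after cyclic loess. The list had a camera adjusted p of 0.241, and its median was -0.01 without vehicle replicate 1.

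Antigen presentation genes passed the test neither as lists nor one by one, and the vehicle arrays differed in them. H2-Eb1, an MHC class II beta chain, had 6.66 and 7.93 on vehicle replicates 1 and 5 and 8.45 and 9.03 on antibiotics replicates 8 and 9, a log2 fold change of 1.44 ± 0.47 SE. H2-Ab1 had 0.95 ± 0.38 SE and H2-Aa, its alpha chain partner, 0.45 ± 0.30 SE. H2-Ob, which modulates peptide loading, had 6.72 ± 0.01 and 7.31 ± 0.12, and the co-stimulatory ligand gene Cd80 had a log2 fold change of 0.53 ± 0.34 SE. In the list of MHC class II and co-stimulation, 11 of 15 measured members were higher, with a median of 0.26 and a camera adjusted p of 0.206 (adjusted p = 0.856 with an estimated correlation). That median was 0.03 without vehicle replicate 1. In the MHC class I list 14 of 17 were higher, with a median of 0.18 (0.06 without vehicle replicate 1) and an adjusted p of 0.297. The class I list mean was 8.38 and 8.76 on vehicle replicates 1 and 5 against 8.83 and 8.73 on antibiotics replicates 8 and 9. The class I gene H2-D1 was 6.95 and 8.97 on the vehicle arrays and 8.97 and 8.73 on the antibiotics arrays, and Tapbp, H2-T23 and Psmb8 had log2 fold changes of 0.57, 0.35 and 0.39.

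Type I interferon response genes were higher with antibiotics in 21 of 28 measured members, with a median log2 fold change of 0.22. Xaf1 had 6.33 ± 0.46 with vehicle and 7.41 ± 0.07 with antibiotics (SD, n = 2 each). Oas2, an antiviral RNA sensor, had 6.36 and 5.06 on the vehicle arrays against 6.99 and 6.48, and Irf7, a transcription factor that amplifies interferon production, had 6.37 and 5.60 against 6.73 and 6.72. Ifit2 had a log2 fold change of 0.91 ± 0.43 SE. The camera adjusted p of the list was 0.201, and its median was 0.06 without vehicle replicate 1. In that setting Oas2 (limma adjusted p = 0.00140) and Irf7 (adjusted p = 0.0487) passed one by one, while without vehicle replicate 5 Oas2 had a log2 fold change of 0.38 (adjusted p = 0.330) and Irf7 of 0.35 (adjusted p = 0.356).

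Interferon gamma response genes had a median of 0.05, with 13 of 24 higher and an adjusted p of 0.661, and matched random lists had 0.13. The GTPase genes Igtp, Gbp7 and Irgm2 had log2 fold changes of 0.69 ± 0.28, 0.63 ± 0.27 and 0.63 ± 0.36 SE, and Irf8, a transcription factor of the myeloid lineage, had 0.75 ± 0.32 SE. The median turned negative under all 3 other scalings, from -0.08 to -0.05, and was 0.11 without vehicle replicate 1.

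Inflammatory signalling genes lay on both sides of 0. Tnf had 5.91 ± 0.07 with vehicle and 5.79 ± 0.29 with antibiotics, and Il1b had 9.05 ± 0.55 and 8.80 ± 0.56 (SD, n = 2 each), and both differences were smaller than their SE (-0.12 ± 0.29 and -0.26 ± 0.41). Ptgs2, the inducible cyclooxygenase, had a log2 fold change of -0.68 ± 0.32 SE and Tnfaip3, an inhibitor of NF-kappaB signalling, -0.43 ± 0.30 SE, while Tnfaip2 had 0.71 ± 0.42 SE and Nfkbid 0.48 ± 0.33 SE. Of the 31 measured members of the NF-kappaB and TNF list, 17 were higher, the median was 0.08 and the camera adjusted p was 0.985. That median turned negative under the 3 other scalings, from -0.09 to -0.02, and was 0.07 without vehicle replicate 1.

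Map3k7, which encodes the kinase TAK1, had 7.57 ± 0.56 with vehicle and 7.87 ± 0.17 with antibiotics, a log2 fold change of 0.30 ± 0.35 SE that was -0.10 without vehicle replicate 1. In its pathway Map2k4 had -0.88 ± 0.28 SE, Traf6 0.55 ± 0.28 SE, Ikbkg -0.49 ± 0.30 SE and Map2k3 -0.44 ± 0.30 SE. The list of TAK1 and MAP kinase genes had 9 of 16 higher, a median of 0.24 (-0.10 without vehicle replicate 1) and a camera adjusted p of 0.985. Inflammasome genes were higher in 12 of 14, with a median of 0.27 and an adjusted p of 0.241, and P2rx7, an ATP-gated channel, had 0.61 ± 0.30 SE, Nlrp3 0.81 ± 0.41 SE, Nlrc4 0.63 ± 0.34 SE and P2rx4 0.38 ± 0.28 SE. That median was 0.12 without vehicle replicate 1.

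The immediate early list, which also holds genes induced by tissue dissociation, was split, with 12 members higher and 12 lower. Besides Dusp1, Jun had a log2 fold change of 1.11 ± 0.42 SE, while Ier2 had -0.96 ± 0.32 SE and Klf4 -0.85 ± 0.30 SE. The median was 0.02 and the camera direction was down, with an adjusted p of 0.985. The median turned negative under the 3 other scalings and was -0.01 without vehicle replicate 1.

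Among metabolic genes, Bbox1, the last enzyme of carnitine synthesis, had low log2 values of 3.06 ± 0.11 with vehicle and 3.29 ± 0.04 with antibiotics (SD, n = 2 each). The carnitine transporter gene Slc22a5 had 5.70 ± 0.15 and 6.29 ± 0.02, and the fatty acid oxidation genes Acadm, Etfa and Echs1 had log2 fold changes of 0.75 ± 0.29, 0.83 ± 0.38 and 0.64 ± 0.29 SE. Of the 26 measured genes of carnitine synthesis and fatty acid oxidation, 20 were higher, with a median of 0.14 (0.07 without vehicle replicate 1) and a camera adjusted p of 0.297, where matched random lists had a median of 0.12. Cholesterol biosynthesis had 13 of 18 higher, a median of 0.20 and an adjusted p of 0.297, with Mvd at 0.67 ± 0.37 SE, Cyp51 at 0.60 ± 0.34 SE and Fdft1 at -0.60 ± 0.27 SE. Nsdhl was 5.19 and 6.58 on the vehicle arrays against 6.83 and 7.22, and its log2 fold change of 1.14 ± 0.48 SE was 0.44 without vehicle replicate 1 and 1.83 without vehicle replicate 5. The median of the list was 0.14 without vehicle replicate 1. Glycolysis had 13 of 20 higher, a median of 0.21 (-0.08 without vehicle replicate 1) and an adjusted p of 0.651, with Pfkfb3 at 0.55 ± 0.37 SE, Tpi1 at 0.48 ± 0.37 SE, Pfkp at 0.37 ± 0.27 SE and the hexokinase gene Hk1 at -0.37 ± 0.28 SE.

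Oxidative phosphorylation genes had 17 of 33 members higher and a median of 0.02, and the median was negative under the 3 other scalings. Atp5b had 9.28 ± 0.22 and 10.02 ± 0.11, Ndufv1 had 5.01 and 6.81 on the vehicle arrays against 7.17 and 7.29, Sdha had a log2 fold change of 0.60 ± 0.29 SE, and Cyc1 had -0.54 ± 0.27 SE. The mean over the list was 0.08 while the camera direction was down, with an adjusted p of 0.979. Without vehicle replicate 1, which leaves 1 vehicle array, the median was -0.26. Cytosolic ribosomal protein genes had 20 of 28 members lower, a median of -0.05 and an adjusted p of 0.314, with Rps24 at -0.33 ± 0.27 SE, Rps19 at -0.30 ± 0.27 SE, Rpl22 at -0.34 ± 0.37 SE and Rpl8 at 0.33 ± 0.33 SE. Rpl8 was -0.01 without vehicle replicate 1, and Rpl22 was 0.12 without vehicle replicate 5. Without vehicle replicate 1 their median was -0.34 with an adjusted p of 2.71e-05 (adjusted p = 0.912 with an estimated correlation), and without vehicle replicate 5 it was 0.18.

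In the remaining lists, complement genes had a median log2 fold change of 0.18 with 9 of 14 higher (adjusted p = 0.464), and Cfp, which encodes properdin, had 0.97 ± 0.33 SE, Cfb 0.68 ± 0.28 SE and C1qa 0.60 ± 0.28 SE, while C2 had -0.46 ± 0.27 SE. Lysosome and phagocytosis genes had a median of 0.16 with 18 of 25 higher (adjusted p = 0.297), which was 0.00 after quantile normalization, with Ctso at 0.82 ± 0.27 SE, Gla at 0.61 ± 0.29 SE, the Fc receptor gene Fcgr1 at 0.42 ± 0.27 SE and the protease gene Ctsk at -0.66 ± 0.43 SE. TGF-beta signalling genes had a median of 0.23 with 11 of 16 higher (adjusted p = 0.297), and Nrros, which presents TGF-beta on microglia, had 7.56 ± 0.04 and 8.18 ± 0.20, while Smad2 had 0.70 ± 0.36 SE, Skil 0.59 ± 0.29 SE and Ski 0.48 ± 0.28 SE. These 3 medians were 0.12, 0.01 and 0.02 without vehicle replicate 1.

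Cell cycle genes had a median of 0.14 with 17 of 28 higher (adjusted p = 0.651), which turned to -0.0082 after quantile normalization, -0.040 after cyclic loess and -0.15 without vehicle replicate 1. Cdk1 had 4.29 and 6.48 on the vehicle arrays against 7.23 and 7.21, Bub1 had -0.80 ± 0.30 SE, Cdc20 0.64 ± 0.31 SE and Aurkb 0.53 ± 0.28 SE. Oxidative stress and NADPH oxidase genes had a median of -0.08 and a mean of 0.03 with 12 of 19 lower (adjusted p = 0.717), and among them Cybb, the catalytic subunit of the phagocyte oxidase, had 0.92 ± 0.34 SE, Gclc 0.85 ± 0.34 SE, Gpx1 -0.34 ± 0.31 SE and the catalase gene Cat 0.27 ± 0.34 SE, which was -0.12 without vehicle replicate 1. The list of aryl hydrocarbon receptor targets, which also holds the receptor gene Ahr and its partner gene Arnt, had a median of -0.09. In it 9 of 13 were lower (camera adjusted p = 0.622), and 7 of 13 had a mean above the chemosensory level of 5.16. Tgfa had -1.04 ± 0.41 SE, Socs2 0.86 ± 0.37 SE, Arnt 0.62 ± 0.27 SE and Cyp1b1 -0.38 ± 0.45 SE. The value of Cyp1b1 was 0.16 without vehicle replicate 1 and 0.0017 without antibiotics replicate 9. Glutamate receptors and transporters had a median of -0.10 with 12 of 19 lower (adjusted p = 0.297), which turned positive under both filters on dim genes. In that list 2 of the 19 members had a mean above the chemosensory level of 5.16. Gria4 had log2 values of 3.99 ± 0.84 with vehicle and 3.05 ± 0.24 with antibiotics and Gria2 had 4.35 ± 0.81 and 3.47 ± 0.42 (SD, n = 2 each), in both groups under that level. Grm2 had 5.41 ± 1.11 and 4.45 ± 0.51 and Grin2b had 4.51 ± 0.02 and 5.33 ± 0.17, each with 1 group mean under it. The medians of these last 3 lists were -0.12, -0.18 and -0.02 without vehicle replicate 1.

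Markers of monocytes, which carry more CD45 than microglia and which the gate should largely leave out, were higher with antibiotics in 16 of 19 measured members. Their median was 0.24, with a camera adjusted p of 0.201. The arrays of the groups did not overlap in 4 of the 19, all of them higher, where 35.0% of all genes did not overlap. Above the chemosensory level of 5.16 lay the means of 10 of the 19. Ly6c2, the surface antigen of inflammatory monocytes, had log2 values of 3.49 and 3.86 on the vehicle arrays and 5.22 and 5.21 on the antibiotics arrays, a difference of 1.55 ± 0.29 SE. Its vehicle values lay near the medians of the chemosensory receptor genes on those arrays (4.10 and 3.58), so the difference in log2 value is not read as a fold of transcript. It was the 1 gene of any list to pass when p-values were adjusted over the list alone (limma adjusted p = 0.0236), and its adjusted p over all genes was 0.868. The first of these values is not adjusted across the 33 lists, so 1 such gene can arise by chance. The mean of Ly6c2 lay under the 95th percentile of the chemosensory receptor genes (5.16), so that filter leaves it out. Binding of transcripts of the near-identical Ly6c1 to its probes was not tested. Ccr2, the chemokine receptor of the same cells, had 4.24 ± 0.26 and 4.62 ± 0.18, Vim had 5.53 ± 0.15 and 6.02 ± 0.24, and Tgfbi had 4.43 and 6.18 on the vehicle arrays against 6.80 and 6.50. The median of the list was 0.20 without vehicle replicate 1.

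Neutrophil markers were lower in 11 of 15, with a median of -0.23 and an adjusted p of 0.206, and the median was -0.20 without vehicle replicate 1. S100a8, a calcium-binding protein of neutrophils, was 5.85 on vehicle replicate 1 against 3.69 on vehicle replicate 5 and 3.74 and 3.16 on the antibiotics arrays. Ngp was 5.71 against 4.27, 4.66 and 3.61, Cxcr2 had -0.56 ± 0.32 SE, and Csf3r, which other myeloid cells also express, had 0.62 ± 0.28 SE. With the dim genes left out by the level of the chemosensory receptors, 3 of the 15 markers stayed and their median was 0.31. Most of the lower markers were thus dim. Border-associated macrophage markers had a median of 0.00 with 8 of 15 higher (adjusted p = 0.651) that turned negative after cyclic loess and centring, and Siglec1 had 6.20 ± 0.04 and 7.12 ± 0.11 and Gas6 had 0.52 ± 0.27 SE. Mrc1, the mannose receptor, was 3.62 and 5.62 on the vehicle arrays against 5.76 and 6.13, and Stab1 was 6.16 and 7.81 against 7.90 and 7.87.

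Lymphocyte and dendritic cell markers did not pass by camera; T and B cells lack CD11b for the most part. T and NK cell markers had a median of 0.09 with 10 of 19 higher (adjusted p = 0.705) that turned to -0.0085 with arrays centred, with Il2rb at 0.55 ± 0.30 SE, Cd3g at 0.53 ± 0.32 SE, Icos at 0.34 ± 0.29 SE and Klrd1 at -0.52 ± 0.30 SE. B cell markers had a median of 0.19 with 6 of 9 higher (adjusted p = 0.705), and Ebf1 had 0.53 ± 0.33 SE, Cd79b 0.48 ± 0.49 SE, Pax5 0.41 ± 0.32 SE and Vpreb3 0.28 ± 0.29 SE. Dendritic cell markers, which include Klrd1, had a median of 0.01 with 6 of 12 higher and a camera direction of down (adjusted p = 0.786), and the median was -0.09 with arrays centred. Among them Zbtb46 had 0.60 ± 0.33 SE, Flt3 -0.51 ± 0.34 SE and Itgae -0.62 ± 0.46 SE. Cd79b was -0.23 and Itgae 0.02 without vehicle replicate 1. Without vehicle replicate 1 these 3 medians were -0.01, 0.10 and 0.02.

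Markers of other brain cells and of erythroid cells, which for the most part carry no CD45 or CD11b and should not pass the sort, varied at low to middle signal. Astrocyte markers had a median of 0.22 with 9 of 13 higher (adjusted p = 0.314), and Gfap had 4.87 ± 0.32 and 5.32 ± 0.05, Aldh1l1 had 0.45 ± 0.31 SE, Sox9 0.41 ± 0.36 SE and Fgfr3 0.39 ± 0.43 SE. Oligodendrocyte markers had a median of 0.03 with 7 of 13 higher (adjusted p = 0.705) that turned to -0.07 with arrays centred, with Mobp at 0.95 ± 0.35 SE, Olig2 at 0.91 ± 0.39 SE, Mog at 0.82 ± 0.39 SE and Cspg4 at 0.56 ± 0.31 SE. Endothelial and pericyte markers had a median of 0.20 with 8 of 14 higher (adjusted p = 0.661), with Vtn at 0.93 ± 0.32 SE, Pecam1 at 0.53 ± 0.28 SE, Kcnj8 at 0.41 ± 0.29 SE and Acta2 at -0.62 ± 0.32 SE. Neuronal markers had a median of -0.07 with 9 of 14 lower (adjusted p = 0.661), with Map2 at 0.70 ± 0.41 SE, Syt1 at 0.62 ± 0.33 SE, Nefl at -0.55 ± 0.32 SE and Slc32a1 at -0.44 ± 0.31 SE. Erythroid markers had a median of 0.20 with 2 of 3 higher (adjusted p = 0.793), with Slc4a1 at 0.61 ± 0.53 SE, Klf1 at 0.20 ± 0.33 SE and Alas2 at -0.19 ± 0.31 SE. Fgfr3, Slc4a1 and Klf1 had -0.22, -0.11 and -0.11 without vehicle replicate 1, and Alas2 had 0.092 without antibiotics replicate 9. Without vehicle replicate 1 the medians were 0.23 for astrocytes, 0.19 for oligodendrocytes, 0.21 for endothelial cells, -0.01 for neurons and -0.11 for erythroid cells.

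Over the 33 lists, 0 had an adjusted p under 0.05 by limma's camera with a preset correlation of 0.01, and 6 had an unadjusted p under 0.05, 5 of them up and 1 down. With an estimated correlation, by fry and by camera on ranks 0 lists passed, with smallest adjusted p of 0.856, 0.514 and 0.243. Set against random lists matched on mean expression, 21 list medians lay above and 12 below the random median. Outside the middle 95% of the random medians were 3 lists, homeostatic microglia (98.7 percentile), oxidative stress (2.1) and ribosomal proteins (0.62), with oxidative phosphorylation at 3.37 and interferon gamma response at 16.5. Without vehicle replicate 1, homeostatic microglia (85.1) and oxidative stress (9.49) lay inside that range. Below it were then ribosomal proteins (0.01), oxidative phosphorylation (0.02), cell cycle (1.26) and neutrophils (1.77). Above it were oligodendrocytes (97.7), endothelial cells (98.8), monocytes (98.9) and astrocytes (99.05). In that order, 5 of 13, 7 of 14, 10 of 19 and 4 of 13 of their members had a mean above the chemosensory level of 5.16. That setting leaves 1 vehicle array. The percentiles are not adjusted for the 33 lists, and random lists do not carry any movement of members together. Median, mean and camera direction differed in sign in 4 lists, those of oxidative phosphorylation, oxidative stress, immediate early genes and dendritic cells.

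**Figure D3:**
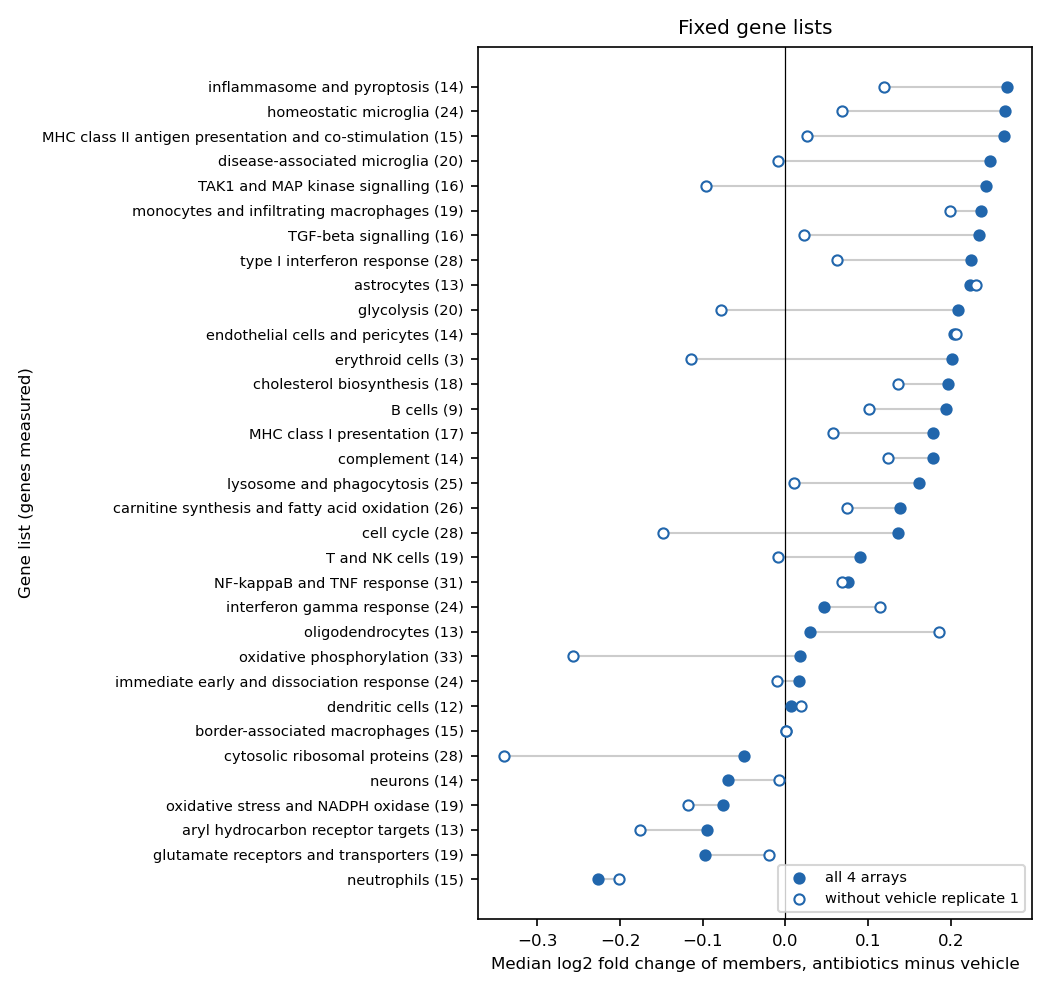
Median log2 fold change of the members, antibiotics minus vehicle (horizontal axis), for each of the 33 lists with the number of genes measured (vertical axis). Filled points use all 4 arrays and open points leave out vehicle replicate 1; the medians run from -0.23 for neutrophils to 0.27 for inflammasome and homeostatic genes with all arrays, and the ribosomal protein list has the lowest open point at -0.34.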

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

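Chosen only after the data were seen were the 2 settings that leave out vehicle array 1 with an estimated correlation or after quantile normalization of the other 3 columns. No paired analysis was possible because the groups share no replicate number. The count of 0 genes past limma's adjusted p of 0.05 held under each scaling, filter, moderation and weighting, and ended when a vehicle array was left out, where the lone array was assumed to vary like the other group: leaving out each array in turn gave 0 to 5950 genes (67 without vehicle replicate 1, 5950 without vehicle replicate 5), 100 to 1896 genes at least 2-fold higher and 38 to 1226 lower, and 0 to 2 lists. Without vehicle replicate 5 the groups part along the difference of vehicle replicate 1 from all other arrays. The array weights were 0.475 for both vehicle arrays, so that setting did not weigh vehicle replicate 1 down against vehicle replicate 5. An unadjusted p with a 1.5-fold change gave 569 genes. The main 2-fold counts of 242 higher and 82 lower became 149 higher under cyclic loess, 157 lower with arrays centred, 14 lower without the dim genes set by the chemosensory receptors, which leaves 10824 genes, and 32 lower without the lowest 25%. In the trend and robust setting, where camera used a variance trend only, 1 list passed, homeostatic microglia (median 0.27, camera adjusted p = 0.00824). Its camera adjusted p was 0.856 with an estimated correlation of -0.0026, read on 2 residual degrees of freedom. Its median was 0.07 without vehicle replicate 1. Of the values of single genes outside the left-out arrays, 1 changed sign and 1220 did not. Most of these could not change sign, since filters, moderation and weights equal within a group leave a gene's log2 fold change as it was. Only the other scalings, and the mean of probe sets for genes with several, could turn a sign. Signal limits the dim genes: 10824 of 19505 genes (55.5%) had a mean above the chemosensory level of 5.16.

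Centring the arrays lowered the log2 fold change of every gene by the same amount, and the median over all genes went from 0.05 to -0.05. Most list medians that turned were near 0 with all arrays, and the cause of turns under the other settings was not tested. Under quantile normalization these were interferon gamma response (-0.082), NF-kappaB and TNF response (-0.078), lysosome (-9.0e-05), oxidative phosphorylation (-0.12), cell cycle (-0.0082) and immediate early genes (-0.089). Under cyclic loess they were interferon gamma response (-0.077), NF-kappaB and TNF response (-0.089), oxidative phosphorylation (-0.14), cell cycle (-0.040), immediate early genes (-0.10), border-associated macrophages (-0.013) and the gene Trem2 (-0.0024). With arrays centred they were interferon gamma response (-0.052), NF-kappaB and TNF response (-0.023), oxidative phosphorylation (-0.081), immediate early genes (-0.083), border-associated macrophages (-0.098), T and NK cells (-0.0085), dendritic cells (-0.092) and oligodendrocytes (-0.070). Without the dim genes set by chemosensory receptors, glutamate receptors (0.026) and neutrophils (0.31) turned, and without the lowest 25% glutamate receptors (0.051), border-associated macrophages (-0.0053), neurons (0.028) and oligodendrocytes (-0.32); fewer genes of those lists were then tested.

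Leaving out each array in turn, the log2 fold change ran from -0.43 to 0.96 for Tmem119, from -0.40 to 0.66 for Trem2, from -0.32 to 0.086 for Tnf, from -0.66 to 0.14 for Il1b, from -0.10 to 0.69 for Map3k7, from -0.12 to 1.90 for H2-D1, from -0.91 to 0.16 for Cyp1b1, from -0.12 to 0.66 for Cat, from -0.013 to 0.67 for Rpl8, from -0.79 to 0.12 for Rpl22, from -0.23 to 1.18 for Cd79b, from -1.27 to 0.022 for Itgae, from -0.22 to 0.9997 for Fgfr3, from -0.11 to 1.33 for Slc4a1, from -0.11 to 0.51 for Klf1 and from -0.46 to 0.092 for Alas2. List medians ran from -0.0086 to 0.39 for disease-associated microglia, -0.00039 to 0.11 for interferon gamma response, -0.10 to 0.23 for TAK1 and MAP kinases, -0.26 to 0.31 for oxidative phosphorylation, -0.078 to 0.26 for glycolysis, -0.18 to 0.0017 for aryl hydrocarbon receptor targets, -0.12 to 0.041 for oxidative stress, -0.15 to 0.46 for cell cycle, -0.0096 to 0.063 for immediate early genes, -0.34 to 0.18 for ribosomal proteins, -0.0087 to 0.15 for T and NK cells, -0.042 to 0.065 for dendritic cells, -0.12 to 0.19 for oligodendrocytes and -0.11 to 0.51 for erythroid cells. With vehicle array 1 left out, the oxidative phosphorylation median was -0.26 in the setting with an estimated correlation and -0.28 after quantile normalization. The correlation estimated there was -0.030, under the preset 0.01, and 1 residual degree of freedom was left, so that test cannot show whether correlation between members matters.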

Other observations

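Chosen only after the result was seen were the tests of a change of scale on vehicle replicate 1, of other cells as its whole source and of other splits of the arrays, and the readings of the percentile of other cells and of the estimated correlation of ribosomal genes as leaving their question open. On vehicle replicate 1 after quantile normalization, the median deviation of NF-kappaB and TNF response genes from the other 3 arrays was 0.31, at the 99.88 percentile of random lists matched on mean expression, the highest of the 33 lists. Outside the middle 95% of random lists were also the TAK1 and MAP kinase list (0.29, 98.3 percentile) and, on the lower side, MHC class II and co-stimulation (-0.39, 2.37 percentile). Astrocyte markers lay at -0.45 (3.05 percentile), disease-associated microglial genes at -0.26 (5.83 percentile), interferon gamma response genes at 0.15 (95.1 percentile) and homeostatic microglial genes at -0.04 (51.2 percentile). These percentiles describe 1 array and are not adjusted for the 33 lists.

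The first pattern is the position of vehicle replicate 1. A change of scale was present on that array, where the interquartile range was 1.98 against 2.38 to 2.44. Its median deviation ran from 0.75 in the dimmest genes to -0.39 between 6 and 8 and -0.20 over 9. The bins were set by the other 3 arrays, so a lower correlation with them would also give such a slope without a change of scale. A change of scale with intensity as the whole source is argued against. After quantile normalization its highest Pearson correlation with another array was still 0.896, where the other arrays reached 0.969 or more. A difference confined to transcripts of that mouse's cells, or brought whole by cells of another type in that sort, is argued against, since over chemosensory receptor genes the SD of its deviations was 2.22 times the largest of the other arrays, and 2.14 times over other genes. Some cells of another type beside another source stay open, although the CD45int CD11b+ sort should remove CD45-negative endothelial cells and neutrophils, which carry high CD45. The highest percentile of any list of other cells was 75.36, for endothelial cells and pericytes, and the neutrophil list lay at 60.95. In 6 of the 11 lists most markers were dim, and 3 of 15 neutrophil markers lay above the chemosensory level. S100a8 and Ngp were higher on that array (5.85 and 5.71 against at most 3.74 and 4.66). Csf3r lay between the other arrays (9.63 against 9.42, 10.07 and 10.21). Also open is noise of that hybridization or RNA over all probe sets, with or without a difference of the mouse beside it, and scanner values and RNA quality were not analysed here.

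The second pattern is the 67 genes that passed when vehicle replicate 1 was left out, 54 higher and 13 lower with antibiotics. They may be differences of vehicle replicate 5 alone: vehicle replicate 1 lay on the vehicle side of the midpoint in 29 of the 67 (43.3%), within the 25.4 to 56.7% of 100 simulations of unchanged groups. Of the named genes among them, vehicle replicate 1 lay off the vehicle side in Irf7, Oas2 and Tnfaip2, and on it in Ly6c2, Dusp1, Ahsa1, Lasp1, Nup155, Vhl, Snx17, Wdsub1 and Cask, and all of these but Ly6c2, which is named whatever its values, had been chosen by p-values that used that array. A treatment effect in some of the 67 also stays open, untested. More vehicle mice would be needed to part these.

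The third pattern is the ribosomal protein and oxidative phosphorylation lists, whose medians were -0.34 and -0.26 without vehicle replicate 1. They lay furthest out in that setting. The astrocyte, monocyte, endothelial, oligodendrocyte, neutrophil and cell cycle lists also lay outside the middle 95% of matched random lists. A difference between the remaining arrays that depends on intensity is argued against, since the ribosomal median lay at the 0.01 percentile of matched random lists, the lowest that 10000 lists can give. Ribosomal genes moving together on 1 array, through the cells or the preparation, cannot be told apart from a treatment effect: with an estimated correlation the adjusted p was 0.912, but the estimate itself was 0.011, near the preset value, and the p was lost to a single residual degree of freedom. With all 4 arrays the estimated correlation was 0.72, and the list means were 9.11 and 9.64 with vehicle and 9.29 and 9.35 with antibiotics, so the vehicle arrays lay on both sides.

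The 4 arrays split into pairs in 3 ways, too few for a share under 0.05. The real split gave 569 genes at an unadjusted limma p under 0.05. Vehicle replicate 1 paired with antibiotics replicate 9 gave 716, and paired with antibiotics replicate 8 it gave 231. So 1 other split gave more genes than the real one.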
